A study of Mus musculus with 282 samples.

How the data were processed

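Single cells were isolated with a micromanipulator into lysis buffer and processed by an adapted Smart-Seq2 protocol with Nextera library preparation, per the labels. The deposited tables hold whole-read counts per Ensembl mouse gene identifier, and the submitters' processing notes name SAMtools, Subread 1.5.0 and featureCounts. The genome build, the annotation and the strand setting are not given in the sources used here, so reads from overlapping or antisense genes and from near-identical copies were not told apart. The library carries no molecular identifiers, so reads are not independent molecules, and intervals and floors cover counting error only. The authors' deposited cell tables give the stimulus, the response class, the cell cycle phase and the score of each phase for each cell that they list as passed. How response classes and phase scores were made is not given in the sources used here.

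Each count column was tied to a sample by its well and plate in the labels, and each line of the cell tables likewise. The 357 columns of the count tables that match no sample were not used. The 92 spike-in features (ERCC) were kept out of library sizes and tests, and held 0.17% of the reads of cells in the 1-plate experiment and 1.62% in the 2-plate experiment. The count of cells with identical columns was 0. The 44 samples outside the cell tables entered no comparison. The 55450 gene identifiers were looked up in the reference gene table, and 0 matched. Gene lists, cell type markers, named genes of the NfkB pathway and the mitochondrial filter, all set by symbol, were therefore not analysed here. Predicted genes, pseudogenes and sex-linked genes, which were to be left out of the named genes, could not be left out for the same reason.

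Each sample is 1 cell, so cells are not replicates, and the experiment was the replicate (n = 2). With the experiment as a term in the fits, p-values measure how far differences between conditions or classes varied between these 2 experiments. The labels do not say that the experiments used separate animals or cultures, so that spread may be technical. Counts were summed per experiment and condition for TNF against blank (4 sums of 15208545 to 200524120 reads, 1 residual degree of freedom). For classes they were summed per experiment, stimulus and response class with at least 5 cells (10 sums, 2 residual degrees of freedom). All sums of a fit shared 1 estimate of the spread, which was drawn partly from other genes (4.64 and 4.32 prior degrees of freedom). Oscillatory TNF, transient TNF and non-responsive blank cells were the 3 classes with sums in both experiments. Tests used edgeR 4.0.16 in R 4.3.3 with its default low-count filter, TMM factors, the experiment as a term, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, two-sided. The experiment was a term because the labels show separate flow cells. Standard errors were the absolute log2 fold change divided by the square root of F. The design, the tests and the rule for named genes were set before the data were examined. The rule takes the largest absolute log2 fold changes among called genes with the same direction in both experiments. It was limited afterwards to 2 genes that rose and 2 that fell per comparison, because identifiers could not be paired with names. Where a class had 0 reads in all sums, a floor of 3 reads over the class gave a bound on the fold.

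The fits were tested on simulated counts drawn from the means of each experiment without class effects, with the real library sizes and dispersions. Each of 5 draws had 100 genes changed by 4-fold and 100 by 8-fold. For TNF against blank, 62% of 4-fold and 69.4% of 8-fold changes were recovered, 0 in the wrong direction, and 13% of calls were false. In the class fit, 54.8% and 59.2% were recovered for oscillatory against blank cells with 20.5% false calls, 56.4% and 59.8% for transient against blank cells with 19.1%, and 53.2% and 59.4% for oscillatory against transient cells with 18.3%. False calls were thus more frequent than the nominal 5% in these simulations. Their share among the real calls may differ, since the number of genes that truly changed is not known. With the stricter filter, genes at 10 CPM or more in at least 50% of the sums, 7.78%, 7.56%, 6.84% and 5.73% of calls were false in the same order, and at least 97.4% of 4-fold changes were recovered. Changed genes were drawn from those that each filter kept, 8619 or 8361 with the stricter and 15479 or 16586 with the default filter. The recoveries thus cover different genes, and changes lost to a filter were not counted as missed. The stricter filter was planned as an alternative, and its counts stand beside the others.

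Other settings chosen at that time were DESeq2 1.42.0, relative log expression factors, no filter and a stricter filter on low counts, no experiment term, sums per plate, cells thinned to 458260 reads (214 cells, with 24 too shallow), a detection threshold of 5 reads, and leaving out plates or experiments. Chosen after seeing the data were cells with at least 8000 detected genes (also in sums per plate, with a lower minimum of cells per sum), spike-in factors, classes regardless of stimulus, cells in G2 or M phase, an average of both responding classes, 20 random splits of the non-responsive blank cells, and cyclone phases. The TNF score and the score of oscillatory genes, with their thresholds of 4-fold and a mean of 20 CPM and a pseudocount of 1, were also chosen after seeing the data, as was a version of each with 2-fold. Phases were recomputed with cyclone of scran 1.30.0, whose 667 marker identifiers were all in the tables. Labels were also shuffled 100 times among cells of the same plate. Shares have exact Clopper-Pearson 95% intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for sums, thinning, scores and figures.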

Results

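The transcriptomes of single granulocyte-monocyte progenitors (GMPs), bone marrow cells that give rise to granulocytes and monocytes, were measured after culture under a confocal microscope. The cells came from mice in which p65, a subunit of the transcription factor NfkB, carries GFP and a histone carries mCherry to mark nuclei. Culture lasted 8 h, and single cells were picked by micromanipulator for Smart-Seq2, which amplifies polyadenylated RNA from 1 cell. TNF is a cytokine that activates NfkB. The series title concerns NfkB dynamics and target genes, and the comparisons here address how gene expression differed between GMPs of different stimulus and response class.

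The 282 samples were single wells of 3 plates from 2 experiments, called here the 1-plate experiment (96 samples) and the 2-plate experiment (186 samples). The authors' deposited cell tables listed 238 of them, 67 in the 1-plate and 171 in the 2-plate experiment, with a stimulus and a response class for each. Of these cells, 178 had received TNF and 60 had a blank in the cytokine column, read here as no cytokine. Reads assigned to genes ranged from 182301 to 3380416 per cell, with a median of 1339522. Between 3672 and 10922 genes were detected per cell. Median detected genes were 9981 in the 1-plate experiment, and 9941 on Plate1 and 9579 on Plate2 of the 2-plate experiment. That Plate2 held 26 of the 28 cells with fewer than 8000 detected genes, and 24 of the 28 were TNF cells.

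The authors' cell tables give each picked cell a response class, by a rule that is not given in the sources used here. In the 1-plate experiment, 25 of 51 TNF cells were transient (exact 95% interval 34.8% to 63.4%), 20 were oscillatory (25.8% to 53.9%) and 3 were non-responsive (1.23% to 16.2%). In the 2-plate experiment, 40.2% of 127 TNF cells were transient (31.6% to 49.2%), 28.3% were oscillatory (20.7% to 37.02%) and 14.2% were non-responsive (8.62% to 21.5%). Sustained responses were seen in 5 TNF cells of the 2-plate experiment and in 0 of 51 TNF cells of the 1-plate experiment, which allows a share of up to 6.98%. Of the blank cells, 13 of 16 in the 1-plate experiment and 34 of 44 in the 2-plate experiment were non-responsive. Another 5 blank cells of the 2-plate experiment were called oscillatory. Cells were picked by hand, so these shares describe the picked cells.

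TNF cells were compared with blank cells to find genes that changed with the stimulus. Of 15479 genes tested on the summed reads of each experiment, 64 rose and 5 fell at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg, n = 2 experiments). The median log2 fold change was 2.58 among the genes that rose and -1.86 among those that fell, also with the 2 genes at 0 reads in blank cells set at their bounds. All 69 genes moved the same way in both experiments, and 46 changed by at least 4-fold. In the group where each gene was higher, a median of 88.2% of cells had a read. The files do not pair gene identifiers with names, so genes are given by identifier.

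Among the genes with the largest fitted changes, ENSMUSG00000052234 and ENSMUSG00000037944 rose, with 5605 and 1718 reads in TNF cells and 0 in blank cells of either experiment. They were at least 702-fold and 215-fold higher, with a floor of 3 reads over all blank cells (edgeR adjusted p = 0.042 and 0.048). For ENSMUSG00000052234 this rested on Plate1 of the 2-plate experiment: the 1-plate experiment had 21 of its reads, which is at least 2.37-fold, and all cells without that Plate1 gave at least 3.06-fold. For ENSMUSG00000037944 the bound was 70.3-fold in the 1-plate experiment and 116-fold without that Plate1. Neither passed with DESeq2 (adjusted p = 0.28 and 0.11) or with relative log expression factors (edgeR adjusted p = 0.0505 and 0.056), and ENSMUSG00000037944 did not pass on sums per plate (edgeR adjusted p = 0.060). ENSMUSG00000052234 was detected in 5 of 51 and 14 of 127 TNF cells, and 52.2% of its reads in the 2-plate experiment came from 1 cell. ENSMUSG00000037944 was detected in 12 of 51 and 10 of 127 TNF cells, and 66.3% of its reads in the 2-plate experiment came from 1 cell. ENSMUSG00000036172 fell by 5.03 ± 0.52 on the log2 scale (SE; edgeR adjusted p = 0.034), from 25.8 to 0.67 CPM in the 1-plate and from 3.84 to 0.13 CPM in the 2-plate experiment. Its blank reads were in 1 of 16 and 5 of 44 cells, and 1 cell gave 61.5% of those in the 2-plate experiment. ENSMUSG00000015647 fell by 2.87 ± 0.30 on the log2 scale (SE; edgeR adjusted p = 0.037), from 85.6 to 8.78 CPM in the 1-plate and from 31.1 to 5.49 CPM in the 2-plate experiment. Its reads were found in 6 of 16 and 15 of 44 blank cells, and in 13 of 51 and 32 of 127 TNF cells.

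The number of genes called with TNF depended on the filter, the plates and the scaling. With genes kept only at 10 CPM or more in at least 50% of the sums, a filter that made fewer false calls on simulated data, 250 genes rose and 48 fell, among them all 64 of the 69 genes that it kept. Without Plate1 of the 2-plate experiment, 0 of the 69 genes passed edgeR's test, although all 68 that were tested kept their direction and the median log2 fold change was 2.49, which is 96.9% of its value. A gene outside the 69, ENSMUSG00000056399, passed there (log2 fold change -7.54, adjusted p = 0.017) and is named after its value was seen. That fit had 1261 genes at an unadjusted p under 0.05, and DESeq2 was run only on all cells. Without Plate2, 177 genes passed, 65 of the 69 among them. With spike-in factors, chosen after seeing the data, 2 genes rose and 1 fell, 1 of the 69 among them; all 69 kept their direction and the median was 113.5% of its value. Without the experiment term edgeR called 0 genes, with 880 at an unadjusted p under 0.05.

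Oscillatory TNF cells were set against non-responsive blank cells, so stimulus and response class changed together, because too few TNF cells of the 1-plate experiment were non-responsive to be summed. Of 16586 genes, 298 rose and 92 fell (edgeR, adjusted p under 0.05, n = 2 experiments), all 390 in the same direction in both experiments. The split changed with the settings: 492 rose and 240 fell with the stricter filter, which kept 349 of the 390, all of them called, and 32 rose and 2 fell without the experiment term, all 34 among the 390. With spike-in factors, chosen after seeing the data, 101 rose and 12 fell, 55 of the 390 among them. Median log2 fold changes were 1.87 and -1.40, also with the 2 genes at 0 reads in a class set at their bounds. ENSMUSG00000052234, with 5394 reads in oscillatory cells and 0 in non-responsive blank cells, was at least 1608-fold higher over the same kind of floor (edgeR adjusted p = 0.013). It was detected in 4 of 20 and 6 of 36 oscillatory cells. ENSMUSG00000027073 rose by 9.52 ± 1.06 on the log2 scale (SE; edgeR adjusted p = 0.016) and was detected in 8 of 20 and 15 of 36 oscillatory cells, against 0 of 13 and 6 of 34 non-responsive blank cells. In the 2-plate experiment, 50.1% of its oscillatory reads came from 1 cell. ENSMUSG00000036172 had 0 reads in oscillatory cells and was at least 216-fold lower (edgeR adjusted p = 0.021), with 580 blank reads in 1 of 13 and 3 of 34 cells. All of those in the 1-plate experiment came from 1 cell, as did 96.8% of the 188 in the 2-plate experiment, where the bound was 64.5-fold. DESeq2 did not call it (adjusted p = 0.15). ENSMUSG00000015437 fell by 10.06 ± 0.69 on the log2 scale (SE; edgeR adjusted p = 0.0046), with blank reads in 2 of 13 and 6 of 34 cells, 78.2% of those in the 2-plate experiment from 1 cell. Without Plate1 of the 2-plate experiment, 112 genes were called, 100 of the 390 among them; ENSMUSG00000052234 and ENSMUSG00000027073 did not pass (edgeR adjusted p = 0.53 and 0.64). ENSMUSG00000052234 was then at least 7.85-fold higher, and the log2 fold change of ENSMUSG00000027073 was 3.33, so the size of both rested on that plate. Without Plate2, 273 genes were called, and ENSMUSG00000036172 and ENSMUSG00000015437 did not pass (edgeR adjusted p = 0.20 and 0.53), the latter with a log2 fold change of -6.02. Without Plate1, ENSMUSG00000036172 also missed the threshold (edgeR adjusted p = 0.051), and the log2 fold change of ENSMUSG00000015437 was -13.02. On sums per plate ENSMUSG00000027073, ENSMUSG00000036172 and ENSMUSG00000015437 did not pass (edgeR adjusted p = 0.085, 0.084 and 0.17).

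Transient TNF cells were compared with the same non-responsive blank cells. Of 16586 genes, 19 rose and 3 fell (edgeR, adjusted p under 0.05, n = 2 experiments), with median log2 fold changes of 2.43 and -2.35. ENSMUSG00000000957 rose by 5.77 ± 0.23 on the log2 scale (SE; edgeR adjusted p = 0.0021), from 0.98 to 45.2 CPM in the 1-plate and from 0.90 to 54.05 CPM in the 2-plate experiment. It was detected in 10 of 25 and 18 of 51 transient cells, against 2 of 13 and 5 of 34 non-responsive blank cells. The highest cell gave 55.1% of its transient reads in the 1-plate and 21.8% in the 2-plate experiment. ENSMUSG00000022126 rose by 4.75 ± 0.48 on the log2 scale (SE; edgeR adjusted p = 0.038), and was detected in 11 of 25 and 38 of 51 transient cells, against 2 of 13 and 3 of 34 non-responsive blank cells. The highest cell gave 54.8% of its transient reads in the 1-plate and 33.5% in the 2-plate experiment, and 93.9% of its 345 blank reads in the latter. ENSMUSG00000015437 fell by 5.71 ± 0.53 on the log2 scale (SE; edgeR adjusted p = 0.027), and 78.2% of its blank reads in the 2-plate experiment came from 1 cell. It was detected in 1 of 25 and 8 of 51 transient cells, against 2 of 13 and 6 of 34 non-responsive blank cells. In the 2-plate experiment the shares of cells with a read were thus close, at 15.7% and 17.6%. ENSMUSG00000039109 fell by 2.35 ± 0.24 on the log2 scale (SE; edgeR adjusted p = 0.038), from 71.3 to 14.1 CPM in the 1-plate and from 33.3 to 6.39 CPM in the 2-plate experiment. The highest cell gave 71.3% of its blank reads in the 1-plate and 17.5% in the 2-plate experiment. With the stricter filter on low counts, 86 genes rose and 18 fell. With spike-in factors, chosen after seeing the data, 19 rose and 3 fell, but only 5 were among the 22, and ENSMUSG00000039109 did not pass (edgeR adjusted p = 1). Without the experiment term only ENSMUSG00000000957 passed. Without Plate1 of the 2-plate experiment 8 genes were called, 7 of the 22 among them, and without Plate2 25 were called, 16 of the 22 among them. ENSMUSG00000000957 passed in both, with log2 fold changes of 4.97 and 7.09. Without Plate1, ENSMUSG00000022126 and ENSMUSG00000039109 did not pass (edgeR adjusted p = 0.098 and 0.10), and without Plate2, ENSMUSG00000015437 and ENSMUSG00000039109 did not (edgeR adjusted p = 0.63 and 0.078), while ENSMUSG00000022126 passed with a log2 fold change of 7.21. On sums per plate ENSMUSG00000015437 did not pass either (edgeR adjusted p = 0.54).

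All 19 genes that rose in transient cells were also among the 298 that rose in oscillatory cells, and 1 of the 3 that fell was among the 92 that fell. Both comparisons used the same blank sums. Independent lists of these sizes would share 0.34 genes that rose and 0.017 that fell, and 20 simulations of unchanged classes against shared blank sums gave at most 5 shared calls over both directions, so the gene that fell in both is within what shared sums gave. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 1.98, against 0.74 in the simulations, and their correlation was 0.61, against 0.52. In 20 random splits, chosen after seeing the data, the non-responsive blank cells were parted into 6 and 7 cells in the 1-plate and 17 and 17 in the 2-plate experiment. The correlation was 0.18 to 0.23 when the classes were set against separate parts, and 0.69 to 0.73 against the same part. With separate parts, medians of 23.5 genes rose in oscillatory and 5 in transient cells, and a median of 3.5, at most 12, rose in both. The covariance then had a median of 0.86, against 1.98 with the shared blank sums. Against the same part, a median of 2.5 genes, at most 19, rose in both, so parts with fewer cells lowered this count without separation.

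Oscillatory and transient TNF cells, which had received the same stimulus, were compared directly. Of 16586 genes, 27 were higher and 6 lower in oscillatory cells (edgeR, adjusted p under 0.05, n = 2 experiments), with median log2 fold changes of 1.67 and -4.26. ENSMUSG00000035493 was higher by 3.28 ± 0.21 on the log2 scale (SE; edgeR adjusted p = 0.034), at 298 against 28.8 CPM in the 1-plate and 310.2 against 37.4 CPM in the 2-plate experiment. It was detected in 16 of 20 and 33 of 36 oscillatory cells, against 13 of 25 and 23 of 51 transient cells. ENSMUSG00000039109, which fell in transient against blank cells, was higher in oscillatory than in transient cells by 2.92 ± 0.24 on the log2 scale (SE; edgeR adjusted p = 0.034). Its levels were 121 against 14.1 CPM in the 1-plate and 38.9 against 6.39 CPM in the 2-plate experiment. ENSMUSG00000056071 and ENSMUSG00000056054 were lower in oscillatory cells, with log2 fold changes of -6.90 ± 0.70 and -5.54 ± 0.63 (SE; edgeR adjusted p = 0.040 and 0.048). Of the transient reads of ENSMUSG00000056071, 91.98% and 84.1% came from 1 cell of each experiment, and of those of ENSMUSG00000056054, 94.4% and 69.5%. With the stricter filter on low counts, 211 genes were higher and 48 lower. Without Plate2 of the 2-plate experiment, edgeR called 0 genes, with 1378 at an unadjusted p under 0.05, and all 33 kept their direction; without Plate1 it called 12, 6 of the 33 among them, and DESeq2 was run only on all cells. Without Plate1, ENSMUSG00000035493 and ENSMUSG00000039109 passed (log2 fold changes of 3.86 and 3.19), and ENSMUSG00000056071 and ENSMUSG00000056054 did not (log2 fold changes of -5.29 and -5.21, edgeR adjusted p = 0.32 and 0.18). Without Plate2, the log2 fold change of ENSMUSG00000056071 was -9.05. That gene had 0 oscillatory and 187 transient reads in the 1-plate experiment, and did not pass on sums per plate (edgeR adjusted p = 0.063). With cells of 8000 or more detected genes, chosen after seeing the data, ENSMUSG00000056071 and ENSMUSG00000056054 did not pass (edgeR adjusted p = 0.054 and 0.060). With spike-in factors, chosen likewise, 4 genes were higher and 4 lower, 3 of the 33 among them, and ENSMUSG00000035493 and ENSMUSG00000039109 did not pass (edgeR adjusted p = 0.53 and 0.81). Without the experiment term edgeR called 0 genes, with 817 at an unadjusted p under 0.05, and in cells of G2 or M phase, also chosen after seeing the data, 0 with 869.

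A joint test over oscillatory TNF, transient TNF and non-responsive blank cells called 228 of 16586 genes (edgeR). Without Plate1 of the 2-plate experiment it called 65, and without Plate2 103.

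**Figure D1:**
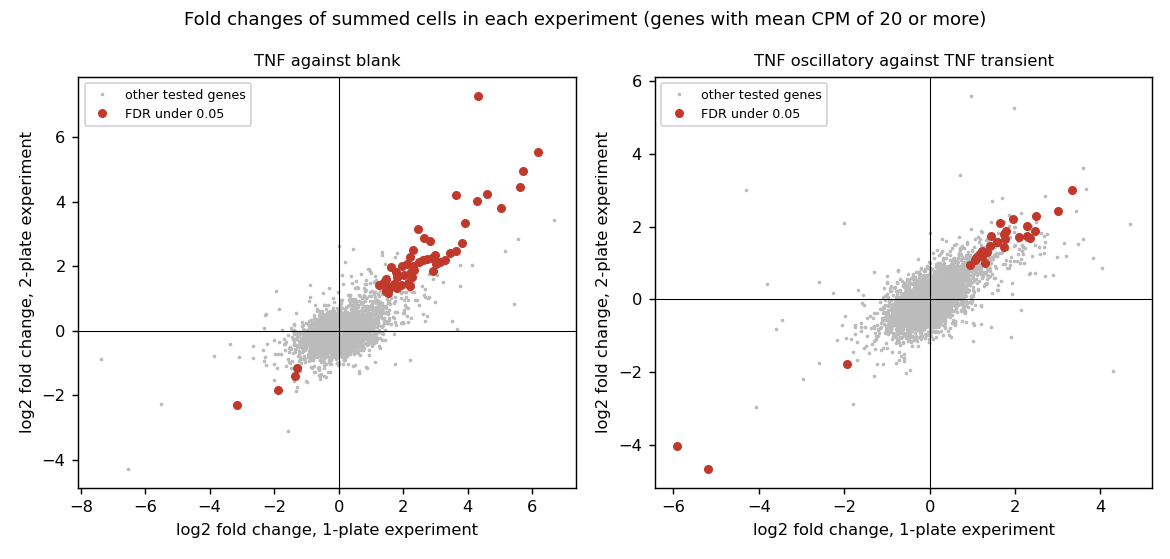
Log2 fold changes of summed cells, log2(CPM + 1), in the 1-plate experiment (horizontal axis) and the 2-plate experiment (vertical axis), for TNF against blank cells (left, 7264 genes) and oscillatory against transient TNF cells (right, 7237 genes). Each point is a gene with a mean of 20 CPM or more, and red points (57 left, 30 right) passed edgeR's test and lie in the lower left and upper right quadrants.

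Fold changes were then set side by side between the experiments. Of 72 genes at least 4-fold higher in TNF than blank cells of the 1-plate experiment, 71 were higher in the 2-plate experiment, with a median log2 fold change of 1.64 there. Of 48 genes at least 4-fold higher in oscillatory than transient cells of the 1-plate experiment, 47 were higher in the 2-plate experiment, with a median of 1.57. Of 11 genes at least 4-fold lower in oscillatory cells of the 1-plate experiment, 7 were lower in the 2-plate experiment. Across genes, Pearson's r between the experiments was 0.61 for TNF against blank cells and 0.69 for oscillatory against transient cells, with Spearman's rho of 0.34 and 0.57. Against non-responsive blank cells, r was 0.67 for oscillatory and 0.39 for transient cells, with rho of 0.48 and 0.15.

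A TNF score was computed for each cell as the mean log2(CPM + 1) of genes at least 4-fold higher in TNF than blank cells of the other experiment. Median scores of oscillatory cells were 5.96 in the 1-plate experiment (40 genes) and 5.78 in the 2-plate experiment (83 genes). Transient cells had medians of 4.01 and 4.12, and non-responsive blank cells 1.47 and 2.75. TNF cells called non-responsive had medians of 4.74 (3 cells) and 4.41 (18 cells). In the 2-plate experiment, 80.6% of oscillatory cells (exact 95% interval 63.98% to 91.8%), 37.3% of transient cells (24.1% to 51.9%) and 9 of 18 non-responsive TNF cells (26.02% to 73.98%) lay above the 95th percentile of non-responsive blank cells. In the 1-plate experiment 18 of 20 oscillatory, 22 of 25 transient and 3 of 3 non-responsive TNF cells did. Scores spread within classes, with an SD of 1.16 over the 36 oscillatory and 1.15 over the 51 transient cells of the 2-plate experiment. There the 5 sustained cells had a median of 3.78 and the 5 blank cells called oscillatory 2.38. Cells are not replicates, so these intervals describe the picked cells.

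**Figure D2:**
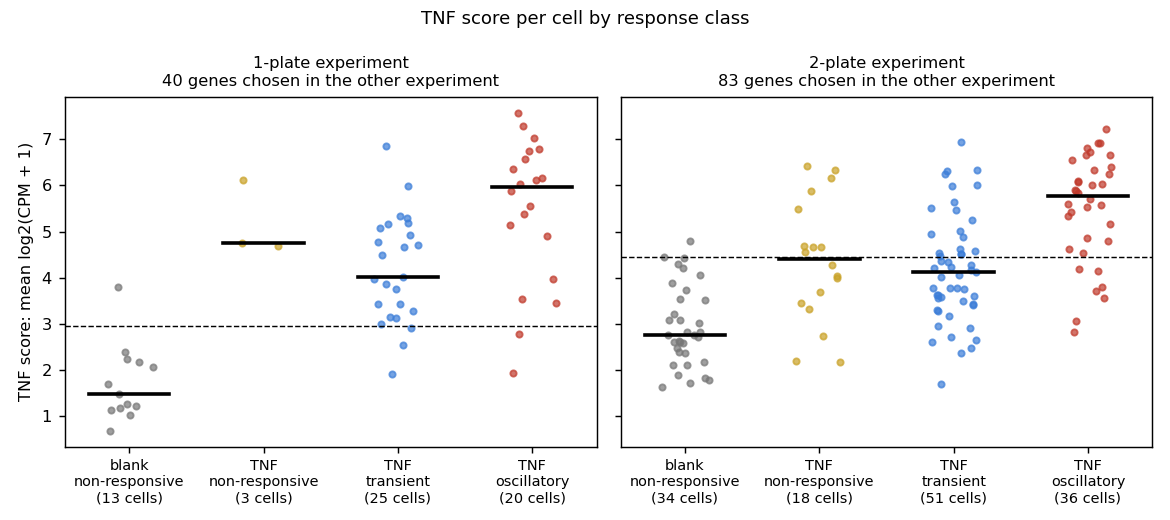
TNF score per cell, the mean log2(CPM + 1) of genes chosen in the other experiment (vertical axis), by stimulus and response class (horizontal axis) in the 1-plate experiment (left) and the 2-plate experiment (right). Points are cells, thick lines are medians and the dashed line is the 95th percentile of non-responsive blank cells; the oscillatory medians of 5.96 and 5.78 lie above it.

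Genes at least 4-fold higher in oscillatory than transient cells of one experiment were likewise scored in the other. In the 1-plate experiment (27 genes) the median score was 4.64 in oscillatory, 2.12 in transient and 1.14 in non-responsive blank cells. In the 2-plate experiment (64 genes) the medians were 4.33, 1.93 and 2.38, so transient cells lay above blank cells in one experiment and below them in the other.

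Cell cycle phases were taken from the authors' calls, and the difference between classes was not tested. In the 1-plate experiment, 2 of 20 oscillatory cells were called S phase (exact 95% interval 1.23% to 31.7%), against 7 of 25 transient cells (12.1% to 49.4%). In the 2-plate experiment, 2 of 36 oscillatory cells were (0.68% to 18.7%), against 12 of 51 transient cells (12.8% to 37.5%). The intervals overlap in both experiments. G2 or M phase was called in 14 of 20 and 22 of 36 oscillatory cells, and in 14 of 25 and 25 of 51 transient cells.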

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

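The ratio of gene reads to spike-in reads moved in opposite directions with TNF in the experiments, a difference that was not tested. The median ratio in TNF cells was 1.38 times that of blank cells in the 1-plate experiment (51 and 16 cells) and 0.885 times in the 2-plate experiment (127 and 44 cells). On the plates of the 2-plate experiment it was 0.945 and 0.757 times. With only cells of 8000 or more detected genes, chosen after seeing the data, it was 1.30 times in the 1-plate and 0.962 times in the 2-plate experiment, and 1.02 times on Plate2 of the latter.

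A signal outside the comparisons was found in samples that the authors' cell tables do not list. Of these 44 samples, 15 had at least 8000 detected genes. In the 1-plate experiment there were 14, with 9051 to 11028 detected genes and 333004 to 1130586 reads, and 1 on Plate2 of the 2-plate experiment had 9568 genes. They carry no stimulus or response class.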

How the results depend on the processing

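Counts of called genes are given in the order TNF against blank (69), oscillatory against blank (390), transient against blank (22), oscillatory against transient (33) and the joint test (228). DESeq2 called 713, 1325, 322, 651 and 1458. The stricter low-count filter gave 298, 732, 104, 259 and 547, and thinned cells 259, 723, 93, 229 and 554. No low-count filter gave 367 for TNF against blank, 84 for transient against blank, 156 for oscillatory against transient and 478 for the joint test. Sums per plate gave 50 and 82 for transient against blank and oscillatory against transient, and 360 for the joint test. With no replicate block, that is without the experiment term, edgeR called 0, 34, 1, 0 and 11 genes, with 880 and 817 at an unadjusted p under 0.05 where the count was 0; DESeq2 was run only with the term. All called genes of the 4 pairwise comparisons kept their direction without it, with median log2 fold changes of 97.2% to 100.01% of their values, and the difference between experiments then enters the spread by construction. Leaving out 1 plate of the 2-plate experiment gave 1 to 177, 112 to 273, 8 to 25, 0 to 12 and 65 to 103. Leaving out an experiment left no residual degrees of freedom, so it gave fold changes without a test. Relative log expression factors kept each count within 1.5 times.

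Of the alternatives chosen after seeing the data, spike-in factors gave 3, 113, 22, 8 and 102, with 1, 55, 5 and 3 of the genes called before in the pairwise comparisons; of the 3, ENSMUSG00000026390 and ENSMUSG00000005339 were not called before. The median log2 fold changes of the genes called before were 113.5%, 125.2%, 116.2% and 109.2% of their values. They moved the median log2 fold change of all genes from 0.03 to 0.42, from 0.02 to 0.56, from 0.03 to 0.41 and from -0.04 to 0.13. Classes regardless of stimulus gave 130, 0 and 87 for the 3 class comparisons, with 982 genes at an unadjusted p under 0.05 where edgeR's count was 0; TNF cells then joined the non-responsive class. The median log2 fold changes of the 390, 22 and 33 genes were then 73.8%, 47.3% and 97.7% of their values, and 119, 0 and 28 of them were called. That of ENSMUSG00000000957 fell from 5.77 to 0.66 and that of ENSMUSG00000022126 from 4.75 to 0.64 (edgeR adjusted p = 0.80 and 0.86). The average of both responding classes gave 136 for TNF against blank. Cells in G2 or M phase gave 0 by edgeR for oscillatory against transient, with 869 genes at an unadjusted p under 0.05, and 31 of the 33 genes kept their direction. Separate parts of the blank cells, in 20 random splits, took the genes that rose in both responding classes from 19 to a median of 3.5. The correlation of the classes' log2 fold changes went from 0.61 to a median of 0.20. Each part held fewer cells. Against the same part the medians were 2.5 genes and 0.71, so the fall in the count came without separation too. Cells with at least 8000 detected genes kept each count within 1.5 times. Of 217 values of the 16 named results under the alternatives, 217 had the same direction, and of the 185 with a test, 125 passed and 60 did not. The named genes were picked for the same direction in both experiments. The 32 values that leave out an experiment therefore had their direction fixed by that choice. The others are refits of the same counts, so the shared direction is no independent support. Where no cause is named, the cause was not tested.

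The share of transient cells of the 2-plate experiment above the blank cells fell to 23.5% with genes chosen at 2-fold. The RNA to spike-in ratio on Plate2 of the 2-plate experiment turned from 0.757 to 1.02 without cells under 8000 genes. A detection threshold of 5 reads gave medians of 8343 genes in the 1-plate experiment and 8654 on Plate1 of the 2-plate experiment, where thinning gave 9087. Cyclone gave the authors' phase in 95.4% of 238 cells and 95.3% of 214 thinned cells. Gene list tests, imaging measurements and the filter on detected genes and mitochondrial reads were not run, since identifiers matched no symbol and the cell tables hold no continuous imaging values. Depth limits genes read in few cells; 1 cell gave over 50% of the reads of 2 of 69, 6 of 390, 1 of 22 and 2 of 33 called genes.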

Other observations

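TNF cells that the authors called non-responsive were compared with the other classes on sums per plate, because only 3 came from the 1-plate experiment. With at least 5 cells per sum, this class had sums only on the 2 plates of the 2-plate experiment (7 and 11 cells). The comparison thus rests on 1 experiment with plates as replicates, where the plan was to give values and no p. Whether plates of an experiment share animals is not given, and if they do, the p-values below are too small. Against non-responsive blank cells, 123 genes were higher and 36 lower (edgeR). Between oscillatory and non-responsive TNF cells 2 genes passed: ENSMUSG00000026675 was higher in oscillatory cells by 1.66 ± 0.17 on the log2 scale, and ENSMUSG00000096054 changed by -3.18 ± 0.34 (SE; edgeR adjusted p = 0.049 for both), named after their values were seen. Between transient and non-responsive TNF cells edgeR called 0 genes, with 1814 at an unadjusted p under 0.05, and DESeq2 was not run on sums per plate. A fit of cells with 8000 or more genes, chosen after seeing the data, also lowered the minimum to 3 cells per sum. The 3 cells of the 1-plate experiment thus entered it, so 2 settings changed at once. Its counts against blank cells were 101 higher and 58 lower, and between TNF classes 2 and 0 (1898 at an unadjusted p under 0.05). The 2 genes were others, ENSMUSG00000020964 and ENSMUSG00000021831. A count that misses the threshold does not show that these TNF cells were alike.

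The bounds of the tests below were written before their results were seen, but after the counts of called genes had been seen. On the TNF score, 50% of the 18 non-responsive TNF cells of the 2-plate experiment (exact 95% interval 26.02% to 73.98%) lay above the 95th percentile of non-responsive blank cells. So did 66.7% of the 12 cells with 8000 or more genes (34.9% to 90.08%). Both intervals lay above the share that the percentile leaves for blank cells, which was the bound against each explanation. In the 1-plate experiment all 3 such cells lay above the percentile. Among the picked cells, non-responsive TNF cells thus lay above the percentile more often than blank cells. Cells are not replicates, and the intervals cover cells of 1 experiment and take the percentile as fixed, so they are no test over experiments. A lack of any response and low complexity as the cause of the scores therefore stay open, as do wrongly labelled wells.

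Genes changed between TNF and blank cells were tested against plate position, low complexity and shuffled labels. TNF wells lay in lower columns than blank wells on 2 plates, and in columns 4 to 12 with blank wells in columns 1 to 4 on Plate2 of the 2-plate experiment. Of 177 genes called without that plate, 92.1% kept their direction in it, against position as the whole cause. Their median log2 fold change was 2.03 without that plate and 1.19 in it, signed by the called direction. A part played by position or by the choice of genes stays open. Without cells under 8000 genes the median log2 fold change of the 69 genes was 99.3% of its value, and 0 of 100 shuffles of the stimulus among cells of the same plate called as many genes (highest 10). What else differed between TNF and blank wells stays open, and a response to TNF remains a hypothesis from the same data.

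For genes changed between oscillatory and transient cells, the median signed log2 fold change of the 33 genes in thinned cells was 104.05% of its value. Thinning gives each cell the same number of reads but keeps the expected share of each gene in it. It therefore tests only the weight of deep cells in the sums, and other effects of depth stay open. Shuffles of the stimulus and class labels among all cells of the same plate, blank cells included, called as many genes in 0 of 100 (highest 5). Blank cells thus entered the shuffled classes, so these shuffles do not test the class among TNF cells alone. Cell cycle phase stays open, since in G2 or M phase cells the median was 69.2% of its value, between the bounds of 50% and 80%. A state present without TNF stays open too, since 11.4% of 44 blank cells in the 2-plate and 6.25% of 16 in the 1-plate experiment lay above the median oscillatory cell on the score of oscillatory genes, between the bounds of 5% and 25%. On that score the 5 blank cells called oscillatory, all of the 2-plate experiment, had a median of 1.28, and 1 of the 5 lay above. Non-responsive blank cells there had a median of 2.38. In thinned cells, 0 of 15 blank cells of the 1-plate and 3 of 42 of the 2-plate experiment lay above. A hypothesis is that a state of the progenitor before TNF may go with both the response class and part of these genes. The hypothesis was not tested further.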
